A study of Mus musculus with 23 samples.

How the data were processed

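Total RNA of mouse melanomas was purified with a column kit for DNA and RNA and made into strand-specific (directional) libraries with dual indexes, per the labels' protocols. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4 and aligned with STAR 2.5.3a, and the notes name the genome build mm9. The deposited values are whole-number counts of reads per Ensembl gene, 1 file per library, not normalized, and the authors' summary entries have the names that HTSeq gives them. The counting tool's version, its strand setting and the annotation release are not given in the sources used here. Reads from overlapping genes on the same strand, and from near-identical copies such as ribosomal protein pseudogenes, can therefore be split or lost in ways the counts do not show.

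Each file holds 37620 gene identifiers. The summary entries (reads outside genes, ambiguous, of low alignment quality, not aligned, not unique) name no gene and were kept out of library sizes and tests. Gene counts made up 25.0 to 50.8% of all entries per library, and reads not aligned 10.3 to 36.7%. Reads outside genes made up 25.3 to 66.1% of uniquely placed reads. Symbols were taken by identifier from GENCODE vM21 for GRCm38, which matched 87.45% of identifiers; the 4723 unmatched ones hold 1.704% of the counts. Because that build differs from the authors', it was used for names, gene types and overlaps only and no coordinates are given.

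Groups and numbers came from the titles; the name of the count file of node 4 has a hyphen where its title has another sign, and both were taken as the same library. There were 7 HP primaries, 7 HPN primaries, 7 node libraries and 2 lung libraries, 23 in all. Title numbers of the HPN tumours were read as animals, so node libraries 7a and 7b were summed. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The primaries of both genotypes (14 libraries) were compared in 1 fit. The HPN primaries, nodes and lungs (15 samples after summing) were fitted together for 3 contrasts: node against primary, lung against primary, and lung against node. Each fit used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust quasi-likelihood dispersion (glmQLFit) and glmQLFTest, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes have standard errors derived from the same fit, and CPM values are group means ± SD.

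Of 36 gene lists, all with at least 3 tested members, 33 were tested as lists; the fixed design had the Nme family, the model's loci with the Hgf and Met genes, and sex-linked genes read gene by gene. The 33 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Beside it stand camera with an estimated correlation and fry, whose p tests whether the genes of a list move one way on balance and whose mixed p tests change in either direction. Neither form of fry compares a list with other genes. With the mixed p, 0, 23, 0 and 13 lists were called in the genotype, node, lung and lung against node comparisons. None of the camera calls in the 4 comparisons held with an estimated correlation. A list's median, mean and test differed in sign for 10, 4, 4 and 4 of the 33 lists, in the same order, and 0 of these were called. List members were also counted with p adjusted over the list alone.

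Named genes were, per comparison, Nme1 and Nme2, and the 10 largest rises and 10 largest falls in log2 among genes with an adjusted p under 0.05 and a mean of at least 5 CPM in the higher group. Immunoglobulin and T cell receptor segments, predicted genes and pseudogenes were left out of these and counted as groups. Where none passed, the 5 smallest p in each direction were named and said not to pass. Up to 4 members of each list were named, smallest p first. Csf3r and Adam12 were added, to complete counts of 5. Where a group had 0 counts for a gene, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts only levels are given.

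Nme1, Nme2 and their sum were also tested by exact two-sided permutation of log2(CPM + 0.5), a test added after the design was fixed. Shares of counts carry 95% Wilson intervals (scipy 1.17.1, Python 3.11.15). Alternatives were DESeq2 1.42.0 (Wald test), its size factors in edgeR, limma voom with quality weights, no filter or a filter of over 1 CPM, all 4 groups in 1 fit, Y-linked expression as a covariate, node and lung as 1 group, nodes of number 7 kept apart, each library left out in turn, and title number as a fixed or random block. Chosen after seeing the data were the batch of 8 libraries with low-quality reads as a term, fits without those 8, the keratinocyte mean as a covariate, structural RNA left out, nodes 3 and 5 left out, and numbers 3 to 7 without the block. So were the list tests, counts of called list members and genes shared by both sites with each library left out, and an exact test of Nme1, Nme2 and their sum that flips the signs of differences within title numbers.

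Pairing was checked on deviations from group means. Numbers shared by nodes and primaries (5) come from titles that read as animals. Over all genes their correlations were 0.254, 0.00164, -0.0826, 0.265 and 0.134, limma's correlation within numbers was 0.105, and sex-linked transcripts matched in 8 of 8 metastases whose number has a primary. Numbers shared by the 2 genotypes (6) had correlations of 0.616, 0.350, 0.560, 0.661, 0.104 and 0.556, all over 0.1, although the genotypes are different animals. Blocked counts and list tests are given beside the results they change, and single genes that lost their call under the block are counted with the other settings.

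List medians were also taken with members at 3 counts or fewer in a group set to a floor of 3 counts over the group, a check added after the results were seen. The pipeline was tested on simulated data with 200 genes changed in each comparison, drawn from tested genes with a mean of at least 5 CPM. False calls were 5 of 127 for the genotypes, 4 of 139 for nodes, 10 of 105 for lung and 7 of 96 for lung against node. In a simulation of 33 lists with 1 shifted, the shifted list was called and 0 others. Its genes were drawn independently, so it does not test the preset correlation where genes of a list move together. Replicate correlations ran from 0.801 to 0.976 in HP primaries, 0.834 to 0.971 in HPN primaries and 0.921 to 0.983 in nodes, with 0.915 between the lungs, so no library was taken as a repeat of another. Reads themselves, splicing and variants were not analysed here.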

Results

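Gene expression was read as sequencing counts per gene in 23 libraries of total RNA from mouse melanoma, in a model in which ultraviolet light induces tumours that can spread. The labels give 4 groups. HP primaries (7 libraries) are primary melanomas with wild-type Nme1 and Nme2, and HPN primaries (7 libraries) are primary melanomas with 1 copy of each gene mutated. Lymph node metastases (7 libraries) and lung metastases (2 libraries) were both taken from HPN animals. The labels place nodes 3, 4 and 8 at a brachial site, nodes 6 and 7a at a cervical site, node 7b at an inguinal site and node 5 at a lymph node with no further name. Node libraries 7a and 7b share a title number and were summed, which left 6 node samples.

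In units of 1e6, counts assigned to genes came to 25.2, 89.5, 84.0, 28.9, 42.7, 84.9 and 54.2 in HP primaries 1, 3, 4, 5, 6, 7 and 9. HPN primaries 1 to 7 held 23.8, 30.2, 20.4, 38.3, 58.1, 38.3 and 45.5. Nodes 3, 4, 5, 6, 7a, 7b and 8 held 23.9, 33.7, 18.9, 32.6, 37.6, 37.4 and 33.5, and lungs 3 and 4 held 31.2 and 28.5. In 8 libraries (HP primaries 3, 6, 7 and 9, HPN primary 7, and nodes 7a, 7b and 8) the deposited counts include reads set aside for low alignment quality, and in the other 15 that entry is 0. No label says whether the primaries are separate animals, so p-values measure the spread between these samples.

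Nme1 and Nme2 encode nucleoside diphosphate kinases, and Nme1 is known as a suppressor of metastasis. Both targeted genes were lower on average in HPN than in HP primaries. Nme1 (ENSMUSG00000037601) averaged 10.1 ± 2.42 counts per 1e6 counts (CPM; SD, n = 7) in HPN primaries and 16.3 ± 7.20 CPM (n = 7) in HP primaries, a log2 difference of -0.69 (SE 0.27). Nme2 (ENSMUSG00000020857) averaged 0.229 ± 0.122 CPM (n = 7) and 0.471 ± 0.191 CPM (n = 7), a log2 difference of -1.02 (SE 0.38). In the edgeR fit over all genes neither passed (adjusted p = 0.951 for each). An exact two-sided permutation test of log2(CPM + 0.5) over 3432 arrangements gave p = 0.00816 for Nme2, p = 0.0519 for Nme1 and p = 0.0466 for their sum. Adjusted over these 3 tests, the exact permutation p was 0.0245 for Nme2 and 0.0519 for both others. Within the title numbers that both genotypes share, 5 of 6 differences were negative for each gene and number 4 was positive. An exact test of these differences over 64 arrangements was chosen after the other was seen. This exact test gave p = 0.0625 for Nme2, p = 0.0938 for Nme1 and p = 0.0625 for their sum. Under it Nme2 was not called (adjusted exact p = 0.0938). The genotypes are different animals and no label pairs their numbers, so this pairing may have no basis in the design. The smallest exact p that 64 arrangements can give is 0.0312. The groups overlapped. With all 23 libraries scaled together, Nme1 ran from 5.30 to 13.1 CPM in HPN primaries and from 7.69 to 29.8 CPM in HP primaries. Nme2 had 2 to 21 counts per library in HPN primaries and 11 to 41 in HP primaries.

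The level of Nme2 is uncertain. In the annotation used here, which belongs to a later build than the authors' mm9, 573 of its 1171 exonic bases (48.9%) and 418 of the 3342 of Nme1 (12.5%) are shared with Gm20390, a read-through transcript of both genes on the same strand. Gm20390 had 0 counts in all 23 libraries. In the metastases Nme1 ran from 6.01 to 9.01 CPM over the 7 node libraries and from 9.46 to 11.1 CPM over the 2 lung libraries. Nme2 had 3 to 11 counts per node library and 2 to 3 per lung library.

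**Figure D1:**
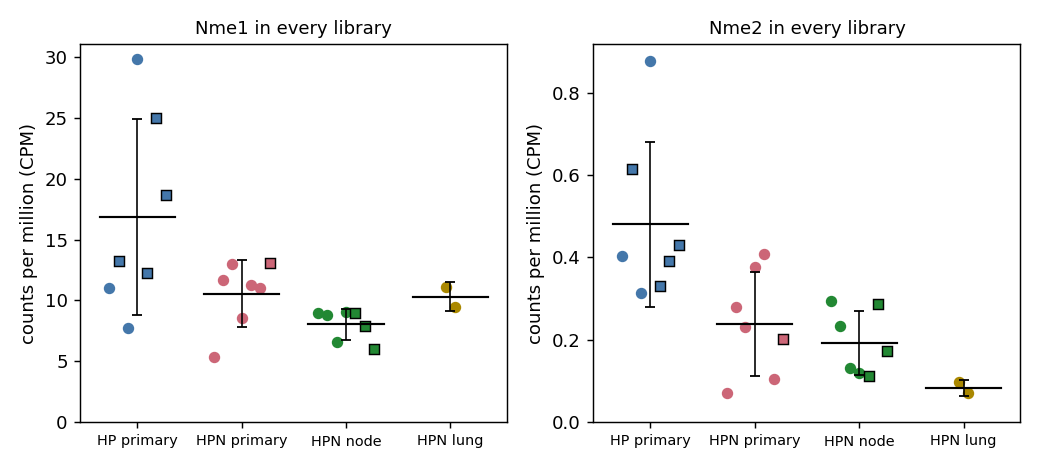
Nme1 and Nme2 in counts per 1e6 counts (CPM, vertical axes) in every library of the 4 groups; the line is the group mean, the bar is its SD, and squares are the 8 libraries with reads set aside for low alignment quality. Nme1 lies between 5.30 and 13.1 CPM in the HPN primaries and between 7.69 and 29.8 CPM in the HP primaries.

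The comparison of genotypes addresses what the loss of 1 copy of Nme1 and Nme2 changes in primary melanomas. Among single genes the differences lay within the spread of the samples. Coq8a, which acts in coenzyme Q synthesis, averaged 86.8 ± 38.0 CPM (n = 7) in HPN primaries and 39.2 ± 7.25 CPM (n = 7) in HP primaries, a log2 difference of 1.15 (SE 0.26). Ccn2, a matrix protein also known as connective tissue growth factor, averaged 45.3 ± 22.9 and 20.2 ± 7.63 CPM (log2 1.16, SE 0.35). Scand1, the methyltransferase gene Smyd3 and the acyl-CoA binding gene Acbd6 had log2 differences of 0.66, 0.49 and 0.54. Trp53inp1, a target of p53, averaged 74.5 ± 14.9 CPM in HPN and 114 ± 27.8 CPM in HP primaries (log2 -0.61, SE 0.18). Tmod2, which caps actin filaments, had a log2 difference of -1.05, and Lrriq3, Zfp709 and the macrophage transcription factor Spic had -0.97, -0.57 and -2.04. These are the 5 smallest unadjusted p in each direction, and none passed (adjusted p = 0.951 for each).

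The edgeR quasi-likelihood test called 0 of 16578 genes between the genotypes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 477 genes, where chance gives 829. DESeq2 also called 0 genes (851 at an unadjusted p under 0.05), as did limma voom (2327). With title number as a block the count was 0 (534 at an unadjusted p under 0.05), and it was 0 in the 9 primaries without low-quality reads (3 HP and 6 HPN; 255 at an unadjusted p under 0.05). Counts simulated at these sample sizes had changes in genes of at least 5 CPM. Of these genes, 35% of those changed by log2 1 and 87% of those by log2 3 were found.

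As groups, 5 of 33 gene lists stood apart from the other genes in HPN primaries by camera with its preset correlation. All 5 calls were for higher expression. Of 18 pigmentation genes 16 had positive log2 differences (median 0.38), among them Pmel, the melanosome fibre protein, at 8371 ± 4895 against 5020.3 ± 3114 CPM, and the melanosome channel gene Oca2 (log2 0.83). The list's camera adjusted p was 0.000174, and adjusted p = 0.999 with an estimated correlation. Of 26 genes of oxidative phosphorylation 23 were positive (median 0.16), with Cox6a1 at 0.59 and Cox5b at 0.73 (camera adjusted p = 2.32e-06; adjusted p = 0.999 with an estimated correlation). Of 18 genes of glycolysis and hypoxia 14 were positive (median 0.32), with Aldoa at 0.63 and Gapdh at 0.68. All 12 skeletal muscle genes were positive (median 1.05), with Myh1 at 144 ± 267 against 52.8 ± 65.3 CPM. Both of these lists had a camera adjusted p of 0.0384 (adjusted p = 0.999 with an estimated correlation). Of 31 ribosomal protein genes 22 were positive (median 0.088, camera adjusted p = 0.0309; adjusted p = 0.999 with an estimated correlation).

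Leaving out single libraries, a test chosen after the results were seen, ended 3 of these 5 list calls. The skeletal muscle call hung on HPN primary 1, in which Myh1 was at 736 CPM. Without it the median turned to -0.49 (camera adjusted p = 0.979), and the call was also lost without HP primary 1, 5, 7 or 9 or HPN primary 4 (0.08 to 0.296). The glycolysis call hung on HPN primary 7, in which Aldoa was at 3515 CPM. Without it the median turned to -0.090 (camera adjusted p = 0.91), and the call was also lost without HP primary 1, 4, 7 or 9 or HPN primary 4 (0.0559 to 0.237). Ribosomal protein genes were lost without HP primary 1, 3, 4 or 9 or HPN primary 5 or 7 (0.135 to 0.448). Pigmentation genes and oxidative phosphorylation kept their calls (highest camera adjusted p = 0.018 and 0.00162).

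No member of any list passed on its own between the genotypes, over all genes or adjusted over the list alone. The fry test called 0 lists (adjusted p = 0.993 for each of the 5). All 17 keratinocyte genes were negative (median -1.11), with the epidermal keratin Krt1 at 188 ± 221 CPM in HPN and 1117 ± 1342 CPM in HP primaries, and the list was not called (camera adjusted p = 0.0773). The mean log2 CPM of that list ran from -0.65 to 9.69 over the HP primaries and from -1.92 to 8.82 over the HPN primaries. With title number as a block over 6 shared numbers, the skeletal muscle call was lost (camera adjusted p = 0.135) and 7 lists were gained. The numbers join different animals of the 2 genotypes, so this block may have no basis in the design. Keratinocyte genes (1.28e-07) and macrophage genes (0.00577) were called lower. Interferon response (7.82e-07), MAPK output (0.00115), invasion proteases (0.0212), mitosis (0.0434) and adipocyte genes (0.0457) were called higher. With an estimated correlation none of the lists was called under the block (lowest adjusted p = 0.801), and fry called 0.

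The comparison of lymph node metastases with HPN primaries addresses how tumours at this site differ from the primary tumours of the same genotype. Genes of lymphocytes rose in the nodes. All 13 B cell genes rose (13 adjusted over the list alone), with a median log2 of 7.69. Ms4a1, which encodes CD20, averaged 156 ± 99.3 CPM (n = 6) in nodes and 0.314 ± 0.312 CPM (n = 7) in primaries, a log2 difference of 8.86 (SE 0.91, adjusted p = 5.51e-05). Pax5, the transcription factor of B cell identity, rose by 8.34. Fcmr, Fcer2a, Cr2, Cd79a, Bank1 and Cd79b, all genes of B cell receptors and their signalling, rose by 7.57 to 8.10 on the log2 scale. The B cell list had a camera adjusted p of 6.91e-32 (adjusted p = 0.0904 with an estimated correlation), and fry gave 8.07e-05.

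Of 16 T cell genes 14 rose in the nodes (14 adjusted over the list alone; median 4.56). Cd4 averaged 189 ± 100 CPM (n = 6) against 5.94 ± 3.27 CPM (n = 7; log2 4.99, SE 0.50, adjusted p = 4.73e-05), and Cd8b1, the kinase gene Lck and the homing receptor gene Ccr7 rose by 5.90, 4.89 and 5.05. The camera adjusted p was 1.01e-19 (adjusted p = 0.143 with an estimated correlation). Of 8 plasma cell genes 7 rose (7 adjusted over the list alone; median 5.29), with the B cell coactivator Pou2af1 at 7.34 and Mzb1 at 6.67 (camera adjusted p = 6.45e-09; adjusted p = 0.191 with an estimated correlation). Of 9 genes of natural killer and cytotoxic cells 7 rose (8 adjusted over the list alone; median 2.44), among them the transcription factors Eomes (3.63) and Tbx21 (3.73) and the granule gene Nkg7 (3.51). That list had a camera adjusted p of 5.71e-05 (adjusted p = 0.504 with an estimated correlation), and with title number as a block 1 of its 9 genes rose. A further 178 called genes were segments of immunoglobulin or T cell receptor genes, and all 178 were higher in the nodes.

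Antigen presentation moved with the lymphocyte genes. All 9 MHC class II genes rose (9 adjusted over the list alone; median 3.84), including H2-Ob (7.31), H2-Oa (6.76) and Ciita (4.94), the master regulator of the class (camera adjusted p = 8.03e-15; adjusted p = 0.143 with an estimated correlation). Of 8 MHC class I genes 4 rose (8 adjusted over the list alone; median 1.29): the immunoproteasome gene Psmb8 (2.22), the peptide transporter genes Tap1 (1.60) and Tap2 (1.25), and H2-K1 (1.55). The class I list had a camera adjusted p of 0.000678 (adjusted p = 0.504 with an estimated correlation), and H2-K1 was lost without node 7 (adjusted p = 0.0581) or node 8 (0.0532). Without node 4, 7 class I genes rose, and with title number as a block none did. Stroma of the lymph node was represented by 8 genes, of which 6 rose (6 adjusted over the list alone; median 3.18). Cxcl13, the chemokine that draws B cells, averaged 101 ± 82.2 CPM (n = 6) against 0.700 ± 0.650 CPM (n = 7; log2 7.17, SE 0.92, adjusted p = 0.000204), and Glycam1, a ligand on high endothelial venules, rose by 8.33. Chst4 and Prox1 rose by 6.22 and 1.13. The stroma list had a camera adjusted p of 5.71e-05 (adjusted p = 0.289 with an estimated correlation), and under the block 2 of its genes rose.

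Myeloid genes rose in part. Of 13 macrophage genes Aif1 (2.97) and C1qa (1.67) rose, the same 2 adjusted over the list alone (median 0.65, camera adjusted p = 0.0211; adjusted p = 0.601 with an estimated correlation). C1qa was lost without node 7 (adjusted p = 0.0691) or node 8 (0.0637). Of 9 neutrophil genes 5 rose (5 adjusted over the list alone; median 2.18, camera adjusted p = 0.0211; adjusted p = 0.601 with an estimated correlation): the granule genes Ngp (3.95), Ltf (4.0) and Camp (3.55), with Retnlg (3.36) and Csf3r (1.96). These 5 hung on few libraries. Without node 7 the adjusted p was 0.0946 for Ngp, 0.0821 for Ltf, 0.109 for Camp and 0.14 for Retnlg. Without HPN primary 4 it was 0.0505 for Ltf, 0.0613 for Camp and 0.061 for Retnlg. Leaving out HPN primary 6 or 7 also ended Camp (0.0581 and 0.0533), and leaving out HPN primary 2, 3, 5 or 6 or node 5 or 8 ended Retnlg (0.0592 to 0.0689). Both list calls were lost with title number as a block (camera adjusted p = 0.221 for macrophage and 0.199 for neutrophil genes), and under it no member of either list rose. The macrophage call was also lost without HPN primary 2 (0.0552) or node 7 (0.051), and the neutrophil call without node 7 (0.0759). The 5 neutrophil genes became 0 without node 7, 2 without HPN primary 4, and 3 without HPN primary 2, 3, 5, 6 or 7 or node 5 or 8; the 2 macrophage genes became 1 without node 7 or 8. Csf3r was among those lost without node 7, and its adjusted p without single libraries is not given here.

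Genes of skin and muscle fell in the nodes. Of 17 keratinocyte genes 15 fell (16 adjusted over the list alone; median -6.80), with Krt14, the keratin of basal epidermis, at 2.86 ± 2.30 CPM (n = 6) in nodes and 534 ± 639 CPM (n = 7) in primaries (log2 -7.53, SE 1.64, adjusted p = 0.0056). Dsg3, Lgals7 and Col17a1 had log2 differences of -7.81, -7.63 and -6.61. Of 11 hair follicle genes 10 fell (11 adjusted over the list alone; median -8.36), with Tchh, the trichohyalin of the inner root sheath, at 1.14 ± 1.01 against 620 ± 1211 CPM (log2 -9.05, SE 2.17, adjusted p = 0.00947). The hair keratins Krt25, Krt26, Krt27, Krt71, Krt72 and Krt75 and the keratin-associated Krtap15 fell by 8.36 to 9.47. Krtap14, Krtap19-2, Krtap19-3, Krt32 and Mt4 had 1 to 3 counts in all nodes together and averaged 8.82, 8.01, 10.7, 7.89 and 6.28 CPM in primaries. Of these 5, Krtap19-2 was lost without node 4 (adjusted p = 0.0506). All 12 skeletal muscle genes fell (12 adjusted over the list alone; median -7.51), led by the myosin gene Myh1 (-8.45) and the creatine kinase gene Ckm (-7.92).

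The camera adjusted p was 2.97e-06 for the keratinocyte list (adjusted p = 0.504 with an estimated correlation), 0.00212 for the hair follicle list (adjusted p = 0.601 with an estimated correlation) and 2.81e-05 for the skeletal muscle list (adjusted p = 0.504 with an estimated correlation). These skin genes varied widely among the primaries. The mean log2 CPM of the keratinocyte list ran from -1.92 to 8.82 there, against -2.02 to 1.36 over the node libraries, and in the SDs given above the spread exceeds the mean. Under the title number as a block, 4 of 17 keratinocyte, 1 of 11 hair follicle and 3 of 12 skeletal muscle genes fell.

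Genes of the melanocyte lineage and its programmes moved less. For these genes and the invasion, matrix, metabolic and mitosis lists, falls in tumour cells were not told apart from an effect of node tissue in the samples. Of 18 pigmentation genes none passed, over all genes or adjusted over the list alone, while 17 were negative with a median of -0.60 (camera adjusted p = 0.00839; adjusted p = 0.601 with an estimated correlation). The list was not called without node 5 (0.0513). Sox10, a lineage transcription factor, was nearest, at log2 -1.27 (adjusted p = 0.0525). Of 15 genes of dedifferentiated or neural crest-like melanoma 3 fell (3 adjusted over the list alone; median -1.28): Nes, which encodes nestin, at 6.06 ± 1.10 CPM (n = 6) against 32.9 ± 18.0 CPM (n = 7; log2 -2.44, SE 0.39, adjusted p = 0.000754), Sox9 (-1.92) and the nerve growth factor receptor gene Ngfr (-2.26). That list had a camera adjusted p of 0.02 (adjusted p = 0.601 with an estimated correlation). It was lost without HPN primary 1 (0.14) or node 4 (0.0537), and without HPN primary 5 its fallen genes were 5. All 15 genes of MAPK output were negative (median -0.99) and 6 of them fell (10 adjusted over the list alone). The ETS factor Etv4 averaged 2.35 ± 0.636 CPM (n = 6) against 11 ± 3.78 CPM (n = 7; log2 -2.22, SE 0.31, adjusted p = 0.000318), and the AP-1 gene Fosl1 fell by 2.88. The MAPK list had a camera adjusted p of 5.74e-05 (adjusted p = 0.318 with an estimated correlation). Its count of 6 fallen genes became 3 with title number as a block, 2 without HPN primary 2 or 7 or node 3, 5, 6 or 8, 3 without HPN primary 5 or node 7, and 10 without HPN primary 1.

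Genes of invasion, matrix and mesenchymal state fell in part. Of 13 invasion proteases and partners 5 fell (5 adjusted over the list alone; median -0.76): the collagenase gene Mmp13 at 0.459 ± 0.219 CPM (n = 6) against 20.9 ± 16.3 CPM (n = 7; log2 -5.47, SE 0.98, adjusted p = 0.00163), Mmp10 (-4.33), Timp1 (-1.49), Mmp14 (-0.76) and Adam12 (-1.62, its values without single libraries not given here). The camera adjusted p was 0.00742 (adjusted p = 0.504 with an estimated correlation). Of 12 genes of the epithelial-mesenchymal transition (EMT) 3 fell (5 adjusted over the list alone; median -0.86, camera adjusted p = 0.00776; adjusted p = 0.344 with an estimated correlation): Twist2 (-2.19), Itga5 (-0.88) and Vim (-0.95). Vim was lost without node 3, 5 or 8 (adjusted p = 0.0562, 0.0605 and 0.0662), and 5 EMT genes fell without HPN primary 1 or 5 or node 4. Of 19 fibroblast and collagen genes 4 fell (7 adjusted over the list alone; median -0.69, camera adjusted p = 0.0118; adjusted p = 0.601 with an estimated correlation): Postn (-1.86), Col1a1 (-2.01), Col6a3 (-1.26) and Col5a1 (-1.06). Col1a1 was lost without HPN primary 3 (adjusted p = 0.0505), node 5 (0.0611) or node 7 (0.0539), and Col6a3 without node 5 (0.0631) or HPN primary 5 (0.0504). Col5a1 was lost without HPN primary 3 or 4 or node 3, 5, 6, 7 or 8 (0.0594 to 0.0865). The 4 collagen genes became 1 with title number as a block, 2 without HPN primary 3 or node 7, and 1 without node 5, and the list was not called without HPN primary 4 (0.0503).

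Metabolic and proliferative genes were lower as lists. Of 26 genes of oxidative phosphorylation 6 fell (7 adjusted over the list alone; median -0.44), with Cyc1 at -0.57, Cox5b at -1.20 and Cox6a1 at -0.98 (camera adjusted p = 2.81e-05; adjusted p = 0.512 with an estimated correlation). That count became 3 without node 5 or 8, 11 without node 4 and 14 without HPN primary 1, and with title number as a block none fell. Of 18 genes of glycolysis and hypoxia 6 fell (9 adjusted over the list alone; median -0.98), with the oxygen sensor gene Egln3 at -3.03 (camera adjusted p = 0.00231; adjusted p = 0.601 with an estimated correlation). No gene of this list was called lower without node 5, 6 or 8 (for Egln3 adjusted p = 0.0553, 0.0504 and 0.0527). Without HPN primary 7 the list had 1 fallen gene, and it had 2 without HPN primary 4 or 5 or node 3 and 2 with title number as a block. All 20 mitosis genes were negative (median -0.75) and 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.000494; adjusted p = 0.601 with an estimated correlation). Of 12 immediate early and stress genes 3 fell (4 fell and 1 rose adjusted over the list alone; median -0.72): Jun (-1.05) and the heat shock genes Hspa1b (-1.96) and Hspa1a (-1.37). That list had a camera adjusted p of 0.0211 (adjusted p = 0.504 with an estimated correlation), and Hspa1a was lost without HPN primary 4 or node 3, 5, 6, 7 or 8 (adjusted p = 0.0501 to 0.0577). The list was not called without node 3 (0.066), and under the block 1 of its genes fell.

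The remaining 11 lists were not called between nodes and primaries, although some members passed. For these members too, changes in tumour cells were not told apart from an effect of node tissue in the samples. The endothelial gene Pecam1 rose by 1.90 and Kdr by 1.10 (2 of 12, and 2 adjusted over the list alone; camera adjusted p = 0.0681). Of 13 metastasis suppressors 4 rose, among them Rhobtb2 (1.03), Arhgdib (1.85) and Cd82 (1.25) (4 rose and 2 fell adjusted over the list alone; 0.76). Napsa (3.6) and Lamp3 (3.90), members of the lung epithelium list, rose (2 of 13, and 2 adjusted over the list alone; 0.907), and Lamp3 is also a marker of mature dendritic cells. Cnp, a myelin gene, rose by 1.16 (1 of 10, and 1 adjusted over the list alone; 0.76), and Ddb2, a gene of nucleotide excision repair, by 0.96 (1 of 22, and 1 adjusted over the list alone; 0.668). Of 31 ribosomal protein genes Rps27 (0.99), Rps23 (0.40) and Rps6 (0.47) rose (1 adjusted over the list alone; 0.115), of 18 interferon response genes 2 rose, among them Irf1 (1.10) (0 adjusted over the list alone; 0.415), and of 20 DNA replication genes Tyms fell by 0.65 (0 adjusted over the list alone; 0.076). Adipocyte (0.952), erythrocyte (0.637) and mitochondrially encoded genes (0.324) had 0 members passing, over all genes or adjusted over the list alone.

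Of these single calls, Cd82 was lost without node 7 (adjusted p = 0.0517), and Lamp3 without node 5 (0.0532). Kdr was lost without node 5, 6, 7 or 8 or HPN primary 1, 2, 3, 5 or 7 (0.0532 to 0.1), Rps23 without node 5, 6, 7 or 8 or HPN primary 1, 2, 3, 4 or 5 (0.0624 to 0.0871), and Rps6 without node 5, 6, 7 or 8 or HPN primary 1, 2, 4 or 6 (0.0577 to 0.0815). Irf1 was lost without node 5, 6, 7 or 8 or HPN primary 2, 3, 4, 5, 6 or 7 (0.0533 to 0.0955), and Tyms without any 1 node or HPN primary 2, 3, 5, 6 or 7 (0.0531 to 0.127). No interferon response gene was called without HPN primary 2 or 4 or node 5, 6, 7 or 8, and 4 were without HPN primary 1. Without node 7, 2 metastasis suppressors rose, without node 4, 4 endothelial genes, and 2 Schwann cell genes without HPN primary 1 or 3 or node 4. Without HPN primary 1 or node 4, 2 genes of nucleotide excision repair rose. A block for title number left 2 metastasis suppressors and 1 ribosomal protein gene called higher, and no endothelial, lung epithelium, Schwann cell, interferon response or DNA replication gene was called.

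Of 10 genes read singly for their place in melanoma 1 rose and 3 fell: Hras (-1.05), Cdkn2b (-1.26) and Cdkn2a (-1.44). With title number as a block, and also in the libraries without low-quality reads, 0 of the 10 rose and 1 fell. Cdkn2b was lost without node 3, 5, 7 or 8 (adjusted p = 0.0514 to 0.0632), and Cdkn2a without node 5, 6, 7 or 8 or HPN primary 2, 3, 5 or 7 (0.0601 to 0.0921). Nme1 had a log2 difference of -0.42 (SE 0.21, adjusted p = 0.151; 8.04 ± 1.31 against 10.7 ± 2.70 CPM, n = 6 and 7). Without HPN primary 1 the difference in Nme1 was -0.58 (adjusted p = 0.026; over all settings adjusted p = 0.026 to 0.464). Nme2 had a log2 difference of -0.33 (adjusted p = 0.593).

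In all, edgeR called 4313 of 19152 genes between nodes and primaries, 2435 higher and 1878 lower, and 22 of 33 lists, 9 higher and 13 lower. None of the list calls held with an estimated correlation, while fry called 12 lists. With title number as a block over the 5 shared numbers, 1307 genes were called (947 higher, 360 lower), and 20 of the 22 list calls were kept (0 with an estimated correlation; fry called 11). With the batch of low-quality reads as a term 3208 genes were called, and in the libraries without such reads 1542 (1153 higher, 389 lower). In the latter 13 of 13 B cell, 12 of 16 T cell and 9 of 9 MHC class II genes rose, and 12 of 17 keratinocyte genes fell. Fewer fell of the invasion proteases (2 of 13), MAPK (2 of 15), EMT (1 of 12) and fibroblast genes (1 of 19). None fell of 18 glycolysis and 26 oxidative phosphorylation genes, and of 8 MHC class I genes 0 rose. Without node 5, whose reads fell outside genes in 66.1% of uniquely placed cases (95% Wilson interval 66.0 to 66.1%), 2731 genes were called. Without nodes 3 and 5, a setting chosen after seeing the data, 1975 were called. Counts simulated for this comparison had changes in genes of at least 5 CPM. Of these genes, 44% of those changed by log2 1 and 91% of those by log2 3 were found. Intervals and floors cover counting error only.

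**Figure D2:**
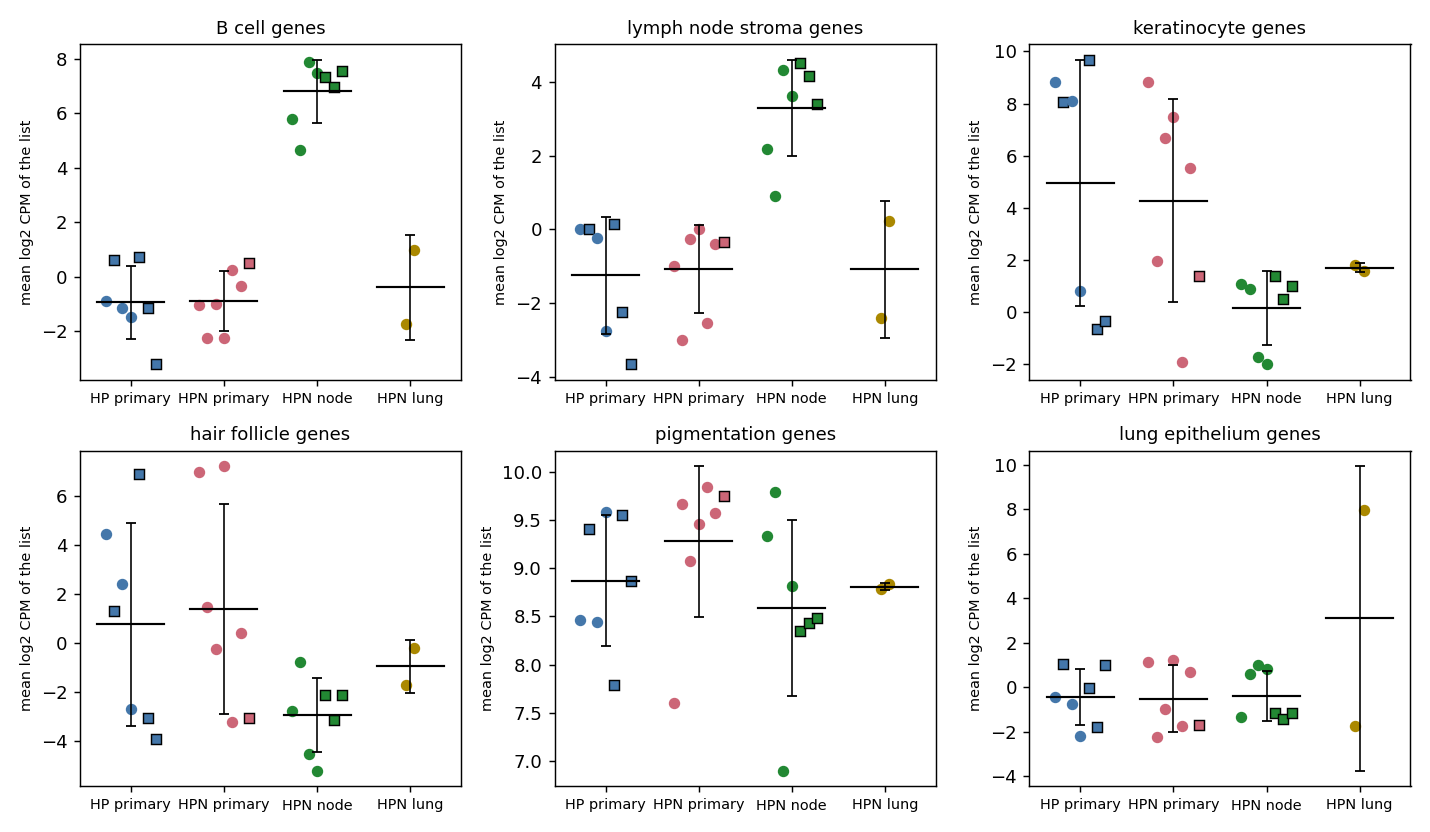
Mean log2 counts per 1e6 counts (CPM, vertical axes) of 6 gene lists in every library of the 4 groups; the line is the group mean, the bar is its SD, and squares are the 8 libraries with reads set aside for low alignment quality. B cell and lymph node stroma genes are highest in the nodes (means 6.80 ± 1.17 and 3.29 ± 1.31), keratinocyte genes spread widely over the primaries, and lung epithelium genes are at 7.95 in lung 4 and -1.75 in lung 3.

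The comparison of lung metastases with HPN primaries asks the same of the other site, with 2 lung libraries. As a list, genes of lung epithelium were high in lung 4 and not in lung 3. Sftpa1 and Sftpb, which encode surfactant proteins, were at 1005 and 913 CPM in lung 4 and at 0.0642 and 0 CPM in lung 3, against at most 0.774 and 0.811 CPM in any HPN primary. Their fitted log2 differences were 11.15 (SE 1.81) and 10.94 (SE 1.76), with an adjusted p of 0.0193 each. Sftpc, the marker of alveolar type II cells, was at 4840 CPM in lung 4 and 0.193 CPM in lung 3. Of 13 tested lung epithelium genes 6 were called higher (12 adjusted over the list alone; median 5.92), and 0 genes of any kind were called without lung 4 (826 at an unadjusted p under 0.05 in edgeR). The list had a camera adjusted p of 4.88e-16 (adjusted p = 0.4 with an estimated correlation) and was not called without lung 4 (0.0643; median -2.88 as fitted, and -1.15 with the 4 members at 3 counts or fewer set to a floor of 3 counts over the group). Its count of 6 called genes became 2 without HPN primary 2, 3, 4 or 5 and 1 without HPN primary 6. Without lung 3, where 16 genes of the list passed the filter, 14 were called.

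Other called genes followed lung 4. Bpifa1, Scgb3a1 and Sec14l3, genes of airway epithelium, and Cxcl15, Lamp3 and Cyp2a5 had log2 differences of 10.43, 9.57, 10.55, 10.14, 9.86 and 9.67. Myh6, a myosin heavy chain of heart muscle, was at 405 CPM in lung 4 and 0 CPM in lung 3 (log2 10.81). Mlc1 was at 23.5 CPM in lung 4 and 0 CPM in lung 3, with at most 0.0369 CPM in any primary. Prx, which the fixed lists held as a Schwann cell gene, had a log2 difference of 3.03. Without lung 4 none of these passed. Lung 3, then the only lung library, had 0 counts of Sftpb, Myh6, Sec14l3, Bpifa1, Cxcl15, Lamp3, Cyp2a5 and Mlc1 and 2 of Sftpa1, and the primaries together had 2 (Mlc1) to 52 (Sftpb) counts of these genes, so no fold is given. For Prx, with 162 counts in lung 3, the log2 difference was -0.17. Of the falls, Cilp, a cartilage matrix gene, averaged 1.02 ± 0.484 CPM (n = 2) in lung against 38.7 ± 26.4 CPM (n = 7; log2 -5.25, SE 0.96, adjusted p = 0.0369). The homeobox gene Hoxd8 averaged 0.168 ± 0.0351 against 5.69 ± 3.97 CPM (log2 -5.05, SE 0.90, adjusted p = 0.0313). Ebf3, named after its values were seen, was the third fall, at 0.0642 and 0.107 CPM in the lungs against 1.32 to 3.91 CPM in the primaries.

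Most of these single calls were also lost when 1 primary was left out. Without HPN primary 2, 3, 4, 5 or 6 the adjusted p of Sftpa1, Sftpb, Myh6, Sec14l3 and Mlc1 was 0.0501, 0.0598, 0.0506, 0.0501 and 0.0712, in that order. Bpifa1, Cxcl15, Cyp2a5 and Prx were lost without any 1 of HPN primaries 2 to 7 (adjusted p = 0.0501 to 0.122), and Scgb3a1 without HPN primary 2, 3, 5 or 6 (0.0501 to 0.0712) or lung 4 (0.991). Cilp was lost without HPN primary 2, 3, 4, 5 or 6 (0.0501 to 0.0782), lung 3 (0.107) or lung 4 (0.863). Hoxd8 was lost without HPN primary 2, 3, 4 or 6 (0.0501 to 0.0712), lung 3 (0.0613) or lung 4 (0.863). Ager, a gene of alveolar type I cells at 394 CPM in lung 4 and 3.05 CPM in lung 3, was lost without lung 4 (0.985) or HPN primary 6 (0.0513), and Lamp3 without lung 4 alone (0.863).

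Camera called 15 of 33 lists between lung metastases and primaries, 4 higher and 11 lower, and with an estimated correlation and by fry it was 0 of 33. Beside lung epithelium, endothelial genes (median 0.97, camera adjusted p = 2.91e-05; adjusted p = 0.445 with an estimated correlation) and erythrocyte genes (2.66, 6.91e-06; adjusted p = 0.445 with an estimated correlation) were called higher with 0 members passing. The Schwann cell list, in which Prx passed (2 members adjusted over the list alone), had a median of 0.20 (0.0159; adjusted p = 0.445 with an estimated correlation). Among the lists called lower no member passed over all genes. Fibroblast and collagen genes (median -1.13) had a camera adjusted p of 4.2e-08 (adjusted p = 0.445 with an estimated correlation) and 7 of 19 fell adjusted over the list alone. Skeletal muscle genes (-5.82) had 3.39e-05 (adjusted p = 0.559 with an estimated correlation) and 7 of 12 adjusted over the list alone. Invasion proteases (-0.52) had 7.97e-05 (adjusted p = 0.445 with an estimated correlation) and 3 of 13, and EMT genes (-0.47) 0.0148 (adjusted p = 0.445 with an estimated correlation) and 2 of 12. Keratinocyte genes (-5.22) had 6.85e-07 and MHC class I genes (-0.73) 0.00106 (adjusted p = 0.559 with an estimated correlation for both). Hair follicle (-6.35, 0.00755), mitosis (-0.31, 0.00321), ribosomal protein (-0.19, 0.00548), interferon response (-0.67, 0.0148) and pigmentation genes (-0.41, 0.015) each had adjusted p = 0.877 with an estimated correlation. With title number as a block 12 lists were called, of which 10 were among the 15. The Schwann cell (0.268), mitosis (0.221), ribosomal protein (0.708), interferon (0.62) and MHC class I (0.197) calls were lost, and adipocyte genes (lower, 0.0315; adjusted p = 0.948 with an estimated correlation) and B cell genes (higher, 0.000119; adjusted p = 0.747 with an estimated correlation) were gained. With an estimated correlation and by fry 0 lists were called under the block.

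Of the 15 list calls 2 withstood the loss of each library. Without lung 4 the lung epithelium (camera adjusted p = 0.0643), pigmentation (0.0968) and Schwann cell lists (0.2) were lost, and endothelial genes were called lower (0.032, median -0.69) and mitosis genes higher (0.00324, median 0.38). Without lung 3 the pigmentation, hair follicle, fibroblast, erythrocyte, ribosomal protein, interferon, MHC class I, EMT and invasion protease calls were lost (0.115 to 0.529). Without HPN primary 1 hair follicle (0.0812) and interferon genes (0.0942) were lost, without HPN primary 2 pigmentation genes (0.057), and without HPN primary 4 hair follicle genes (0.0665). Without HPN primary 5 pigmentation (0.0714) and ribosomal protein genes (0.104) were lost. Without HPN primary 7 it was pigmentation, mitosis, ribosomal protein and interferon genes (0.0624 each) and the Schwann cell list (0.107).

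In total edgeR called 51 of 19152 genes between lung metastases and primaries, 48 higher and 3 lower. DESeq2 called 352 genes (167 higher, 185 lower), and limma voom 0 (657 at an unadjusted p under 0.05). With title number as a block edgeR called 0 (1134 at an unadjusted p under 0.05), and in the libraries without low-quality reads 1. With a filter of over 1 CPM it called 12, with no filter 138, and in a fit of all 4 groups 89. Without lung 4 edgeR called 0 genes (826 at an unadjusted p under 0.05), and without lung 3 393 (390 higher, 3 lower). In both of these fits the lone lung sample is taken to vary like the other groups. Without HPN primary 2, 3, 4, 5, 6 or 7 the count was 10, 8, 16, 11, 7 or 26. Nme1 had a log2 difference of -0.039 (adjusted p = 0.997) and Nme2 -1.50 (adjusted p = 0.684).

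Setting lung against node metastases asks how the sites differ from each other. Lymphocyte genes were lower in lung. All 13 B cell genes fell (13 adjusted over the list alone; median -7.24), with Bank1 at 0.777 ± 0.873 CPM (n = 2) in lung and 157 ± 119 CPM (n = 6) in nodes (log2 -7.67, SE 1.27, adjusted p = 0.0155). Cr2 and Ms4a1 fell by 7.54 and 7.33, and Gpr174, a receptor gene of lymphocytes, by 7.49. The B cell list had a camera adjusted p of 9.44e-21 (adjusted p = 0.189 with an estimated correlation). Of 16 T cell genes 10 fell (15 adjusted over the list alone; median -5.23), with Cd4 at -5.86 (camera adjusted p = 1.47e-16; adjusted p = 0.228 with an estimated correlation). Of 9 MHC class II genes 3 fell (9 adjusted over the list alone; median -3.59): H2-Ob (-6.33), H2-Oa (-5.89) and Ciita (-5.07). Plasma cell genes Pou2af1 (-6.89), Mzb1 (-6.06) and Fcrl5 fell, 3 of 8 (8 adjusted over the list alone; median -5.17). The class II list had a camera adjusted p of 4.64e-10 and the plasma cell list 5.67e-07 (adjusted p = 0.228 with an estimated correlation for both). Lta, Prg2 and Fcrl5 had 1 to 3 counts in both lungs together and averaged 5.31, 10.9 and 6.47 CPM in nodes.

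Of 8 MHC class I genes Tap1 (-2.81) and Tap2 (-2.15) fell (8 adjusted over the list alone; median -2.20, camera adjusted p = 2.97e-06; adjusted p = 0.265 with an estimated correlation). Of 8 node stroma genes Glycam1 (-8.27) and Cxcl13 (-7.52) fell (5 adjusted over the list alone; camera adjusted p = 0.000736; adjusted p = 0.265 with an estimated correlation). Of 9 cytotoxic genes 0 passed (5 adjusted over the list alone; median -3.42, camera adjusted p = 2.23e-05; adjusted p = 0.401 with an estimated correlation). Macrophage (median -1.42, camera adjusted p = 0.0167), ribosomal protein (-0.35, 0.000995) and interferon genes (-1.08, 0.0248) were called lower with 0 members passing (adjusted p = 0.798 with an estimated correlation for each).

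Lung epithelium and heart genes of lung 4 were again high. Of 13 lung epithelium genes 9 were called higher (11 adjusted over the list alone; median 5.96, camera adjusted p = 1.62e-05; adjusted p = 0.465 with an estimated correlation), among them Rtkn2 (4.15) and Ager (5.73). Sftpa1, Sftpb, Sftpc, Slc34a2, Bpifa1, Cxcl15 and Sec14l3 had log2 differences of 10.54 to 10.85, and the cardiac genes Myh6 and Actc1 10.64 and 10.75. Sln, a regulator of the calcium pump in muscle, was at 19.4 CPM in lung 4 and 0.0321 CPM in lung 3 and had 0 counts in all nodes. Its lung mean of 9.71 CPM is at least 726-fold higher against a floor of 3 counts over the nodes. Without lung 4 none of these was called. The log2 difference was -3.07 for Sftpc (6 counts in lung 3), -0.77 for Slc34a2 (5 counts) and -0.27 for Ager (95 counts). Of Sftpb, Bpifa1, Cxcl15, Sec14l3, Myh6 and Actc1 lung 3 had 0 counts, against 9 to 47 over the nodes, and of Sftpa1 2 against 53, so no fold is given.

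Whether the next rises lie in tumour cells was not tested. They could also come with node tissue in the node samples or with lung tissue in the sample of lung 4. Genes of MAPK output stood higher in lung than in nodes, with Etv4 at 11.5 ± 5.42 CPM (n = 2) against 2.35 ± 0.636 CPM (n = 6; log2 2.29, SE 0.39, adjusted p = 0.0163) and Etv1 at 1.94 log2. These were 2 of 15 members (5 adjusted over the list alone; median 0.93, camera adjusted p = 5.34e-06; adjusted p = 0.228 with an estimated correlation). Of 15 dedifferentiation genes Nes (3.49; 68.1 ± 49.2 against 6.06 ± 1.10 CPM) and Sema3c (2.20) were called higher (3 adjusted over the list alone; median 0.94, camera adjusted p = 0.0143; adjusted p = 0.677 with an estimated correlation). All 26 genes of oxidative phosphorylation were positive with 0 passing (median 0.44, camera adjusted p = 1.02e-05; adjusted p = 0.553 with an estimated correlation). Jun rose by 1.5, the single call of 12 immediate early and stress genes (1 adjusted over the list alone; median 0.60, camera adjusted p = 0.0248; adjusted p = 0.553 with an estimated correlation). Erythrocyte genes (4.03, 0.00227; adjusted p = 0.465 with an estimated correlation; 3 of 5 adjusted over the list alone), keratinocyte genes (1.46, 0.042; adjusted p = 0.799 with an estimated correlation) and glycolysis genes (0.71, 0.0342; adjusted p = 0.798 with an estimated correlation) were called higher with 0 members passing over all genes. Nme5 was called higher in lung (log2 2.20, SE 0.60, adjusted p = 0.0483; 1.33 ± 1.15 against 0.287 ± 0.175 CPM), while Nme1 (0.38, adjusted p = 0.47) and Nme2 (-1.17, adjusted p = 0.345) were not. With lung 4 left out, the log2 difference was 0.85 for Nme5 and 0.66 for Sema3c.

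None of these single calls withstood the loss of each library in turn. Without lung 4 the adjusted p was 0.0932 for Bank1, H2-Ob, H2-Oa, Gpr174 and Etv4, 0.0992 for Cd4, Nes and Pou2af1, and 0.158 for Rtkn2. Without lung 3 it was 0.135 for Cr2, 0.108 for Ms4a1, 0.0723 for Gpr174, 0.1 for Etv4, 0.104 for Pou2af1, 0.0735 for Lta, and 0.145 to 0.271 for Glycam1, Cxcl13, Prg2, Mzb1, Fcrl5, Ciita, Tap1, Tap2, Etv1 and Jun. Without lung 4 those 10 genes and Cr2, Ms4a1 and Lta were at 0.114 to 0.172, and Sln, Sema3c and Nme5 at 0.584, 0.637 and 0.626. Leaving out node 5, 6, 7 or 8 ended the calls of Sln, Sftpc, Glycam1, Fcrl5, Sema3c, Mzb1, Nme5, Tap1, Tap2, Ciita and Etv1 (0.051 to 0.0916), and node 3 also those of Etv1 (0.0617) and Nme5 (0.0685). Leaving out node 6, 7 or 8 ended Slc34a2, Prg2, Cxcl13 and Jun (0.0512 to 0.064), and node 8 ended Lta, Cr2, Ms4a1 and Pou2af1 (0.0512 each). Not all folds shrank without lung 4. The log2 difference was then -9.88 for Bank1, -6.20 for Cd4 and 2.72 for Etv4, and it fell to 2.48 for Nes and 1.68 for Rtkn2.

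Counts of called members moved with single libraries too. Without lung 4 no member of any list was called. Without lung 3 there were 4 B cell and 1 T cell genes, and no plasma cell, node stroma, MHC class I, MAPK or stress genes. Without node 4 there were 7 MHC class II, 6 MHC class I, 5 plasma cell, 5 MAPK and 2 stress genes. Without node 5, 6, 7 or 8 the T cell count was 5, 4, 4 or 3, and the plasma cell count was 1 without node 5, 6 or 7, with none left without node 8. Without node 6, 7 or 8 there were 5 lung epithelium genes and no node stroma or stress genes, without node 5 1 stroma gene, and without node 8 7 B cell genes. Without node 5, 6, 7 or 8 there was 1 dedifferentiation and 1 MAPK gene and no MHC class I gene, and without node 3 1 MAPK gene. Of the 18 list calls 10 were lost without some library. Without lung 4 these were dedifferentiation (camera adjusted p = 0.23), lung epithelium (0.156; median -2.10 as fitted and -1.10 with 4 members at the floor) and stress genes (0.0777).

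Without lung 3 the keratinocyte, macrophage, node stroma, erythrocyte, ribosomal protein, glycolysis, interferon and stress lists were lost between lung and node (camera adjusted p = 0.0509 to 0.263). Glycolysis genes were also lost without node 3, 5 or 8 (0.0689, 0.0591 and 0.0515), keratinocyte genes without node 4, 5 or 6 (0.0647, 0.0655 and 0.0816), stress genes without node 3 (0.0667) and interferon genes without node 7 (0.0534).

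In sum edgeR called 966 of 19152 genes between lung and node metastases, 375 higher and 591 lower in lung, among them 71 receptor segments, all lower. Camera called 18 of 33 lists, 8 higher and 10 lower, none with an estimated correlation, and fry called 8. DESeq2 called 2467 genes (769 higher, 1698 lower). With title number as a block edgeR called 0 (2328 at an unadjusted p under 0.05; limma voom with title number as a random block called 30). In the libraries without low-quality reads it called 0 (3319 at an unadjusted p under 0.05), and with that batch as a term 263 (90 higher, 173 lower). Without lung 4 the count was 0 (3240 at an unadjusted p under 0.05), without node 4 2017 (822 higher, 1195 lower), and without node 5, 6, 7 or 8 397, 247, 220 or 138. Without lung 3 the balance turned, with 438 genes called, 414 higher and 24 lower in lung, of which 232 were among the 966. Under the block 18 lists were called, of which 14 were among the first 18. Dedifferentiation (camera adjusted p = 0.0759), keratinocyte (0.888), ribosomal protein (0.41) and interferon genes (0.32) were lost, and adipocyte (lower, 0.0191), fibroblast (lower, 0.00275), mitosis (higher, 0.0408) and DNA replication genes (higher, 0.00358) were gained. With an estimated correlation these 4 had adjusted p = 0.763, 0.724, 0.889 and 0.763, and 0 lists were called under the block. Of the 8 lists that fry called it called 1 under the block, the B cell genes (fry adjusted p = 0.0178).

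At both sites 12 genes were called higher than in the HPN primaries, 0 were called lower and 1 moved in opposite directions. The calls in lung rest on lung 4: without it no gene was called at both sites by edgeR, and without lung 3 92 were. Without HPN primary 2, 3, 5 or 6 the count was 6. They include Foxf1, a transcription factor of lung mesenchyme (log2 3.81 in nodes and 6.01 in lung), the retinoic acid enzyme gene Aldh1a2 (3.85 and 5.66; 19.4 CPM in lung 4 and 0.578 CPM in lung 3), Gata4 (5.05 and 7.26; 4.90 CPM in lung 4 and 0.0642 CPM in lung 3, against at most 0.0610 CPM in the primaries), Lrrn4 (3.73 and 8.98), the cytokine receptor gene Il12rb1 (1.09 and 2.04) and the endothelial gene Clec14a (1.78 and 2.68). In lung 3 Foxf1 was at 1.19 CPM and Il12rb1 at 7.77 CPM, above every HPN primary (at most 0.576 and 3.49 CPM). Clec14a was at 8.64 CPM there, within the primaries (5.64 to 11.5 CPM), and Mlc1, Itih4 and Lamp3 were at 0 CPM. Independent lists of these sizes share 6.1 higher and 0.294 lower genes. In 20 simulations of unchanged groups against the shared primaries the highest count was 0. No gene was changed at either site there, so they do not show what the common primaries add where many genes differ. With the 7 primaries split in 35 ways so that each site had its own, the count ran from 0 to 10 with a median of 0. Of the 12 genes 0 were called at both sites at an adjusted p under 0.01 by edgeR. The smallest adjusted p of any gene in lung was 0.0105, so this count could only be 0.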

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

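Of the tests in this part, the count of B cell genes in the libraries without low-quality reads was set down before its result was seen; the tests of node tissue, splits, pseudogenes, mitochondrial RNA, lung tissue and mislabelling were chosen after.

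Values of 1 sample far from the rest of its group were found in 11 of 210 groups of values, and chance gives about 1 in 20 groups. Among HP primaries, number 3 had 35.87% of its counts in 10 genes (95% Wilson interval 35.861 to 35.881%; next highest 11.35%), and structural RNA took 32.6% of its counts (32.579 to 32.599%). HP primary 5 had a mean log2 CPM of 4.477 for immediate early and stress genes (nearest 5.184). HPN primary 1 was low for Smyd3 (log2 CPM 4.996, nearest 5.594) and for the pigmentation list (mean 7.6, nearest 9.07). HPN primary 2 was low for Tmod2 (2.235, nearest 3.223), for Actc1 (-6.319, nearest -3.254) and for the neutrophil list (mean -3.71, nearest -0.8159). Node 4 alone had counts of Krtap14, Krtap19-2 and Krtap19-3 (log2 CPM -4.584, -3.818 and -3.321, against -6.319 at 0 counts in the other nodes), and its T cell list was low (3.148, nearest 4.706). The effects of the 2 metastatic sites, each against the primaries, differed by a test of the difference itself for 966 genes, which is the comparison of lung with node metastases. In the deposited summary entries, 8 libraries have reads set aside for low alignment quality, 196 to 3709 each.

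Genes of lymphocytes and lymph node stroma were higher in the node metastases, and 2 technical explanations were tested. The batch of low-quality reads is argued against, since in the libraries without such reads 13 of 13 B cell genes rose. Node tissue in the samples is a candidate explanation, in that over the 6 nodes the means of the B cell and pigmentation lists had a Pearson r of -0.82 (exact permutation p = 0.0486) and a Spearman rho of -0.829 (exact permutation p = 0.0583), with 1 relation computed. Without nodes 3 and 4, farthest from the median of the B cell mean, r was -0.784. Over the 4 nodes without low-quality reads r was -0.844 (exact permutation p = 0.125), and the 2 nodes with such reads are too few for an r. The most abundant gene of the B cell list, Ighm (chosen after its values were seen), averaged 1521 CPM in nodes and 11.6 CPM in HPN primaries. Lymphocytes drawn into the tumour at this site, which the labels give as the group, stay open as untested. They too would give a negative r, so r does not tell them from node tissue.

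Between the 8 libraries with low-quality reads and the other 15, 141 of 19694 genes separated without overlap, 140 of them lower in the 8, where 100 shuffles within groups gave at most 3. Reads shared with pseudogenes are a candidate explanation, since 82.31% of the separating genes with a known type are annotated pseudogenes, against 4.544% of the other genes (Fisher's exact p = 7.44e-117). Mitochondrial RNA content is argued against by a bound set after its values were seen, since 6 of 9 mitochondrial genes differ by under 0.3 on the log2 scale while mt-Co2, mt-Co3 and mt-Atp6 differ by -2.09, -1.86 and -2.14. Under the first bound, which needed differences of both signs by over 0.3, the highest difference was 0.2558 and the test decided nothing. No biological explanation was tested, because these 8 libraries are not a group of the design.

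Genes of lung epithelium were high in lung 4 and not in lung 3. A mislabelled lung without tumour is argued against, since the median log2 CPM of the pigmentation list in lung 4 was 8.085, within the 7.303 to 9.565 of the HPN primaries (8.552 in lung 3). Lung tissue in the sample of lung 4 stays open: 10 of 13 lung epithelium genes were over 4 times the highest HPN primary in lung 4 and 0 in lung 3, but this count was set after the pattern was seen and restates it, so it does not test the explanation. The most abundant of these genes were Sftpc, Sftpa1 and Sftpb at 4840, 1005 and 913 CPM. Outside that list, mesothelium genes (Msln 89.8 CPM, Upk3b 62.7 CPM) and heart muscle genes (Myh6 405 CPM, Tnni3 41.6 CPM) were also high in lung 4. In lung 3 they were at 0 to 0.642 CPM. Tissue taken along with the metastasis would give them, but they too were chosen after their values were seen. A difference between the 2 metastases themselves stays open, as untested.

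Other splits of the samples were refitted. For nodes against primaries, 1 of 100 splits, the real one, gave as many as 4313 genes and the highest of the others gave 544. With 100 of 1716 possible splits refitted, the smallest share that can be found is 1 in 100. Chance is therefore argued against but not excluded. For the genotypes the real count was 0, which all 100 of 100 splits reach whatever the samples hold, so the splits do not test it. Of the others 1 was above 0, with 258 genes, and the median was 0. Among splits that part as many number pairs, 1 of 96 gave as many genes for nodes, the highest other with 4295 being the real split with HPN primary 1 moved to the nodes. For the genotypes the highest of the others among 64 such splits gave 1, and a real count of 0 leaves nothing to test there either.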

How the results depend on the processing

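Fits with or without the batch of low-quality reads, without nodes 3 and 5, on numbers 3 to 7 without the block, with the keratinocyte mean as a covariate and without structural RNA were chosen after seeing the data. So were list tests, counts of called list members and of genes shared by both sites with libraries left out, list medians at a floor, and the exact tests of Nme1 and Nme2. The other settings were planned. Of the counts and targeted genes each comparison rests on, 110 values under other settings stayed on their side of the threshold or within 1.5 times and 39 did not. Of values of single genes and of lists with all libraries, 3824 kept direction and side, 1130 kept direction and lost their call, 1 kept direction and gained a call (Nme1 in nodes) and 24, all of single genes, changed sign. Lists with libraries left out are not among these. The cause was not tested unless stated. Where libraries were left out, fewer samples are part of the setting.

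The genotype count was 0 under all 26 other settings, leaving out each library included (lowest and highest 0; 235 to 2327 genes at an unadjusted p under 0.05, the highest with limma voom). Over those settings Nme1 ran from -0.81 to -0.31 and Nme2 from -1.21 to -0.83 on the log2 scale (adjusted p = 0.335 or above for both), and both kept their direction.

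For nodes against primaries (4313 genes) the count moved to 6557 with limma voom, 1542 in the libraries without low-quality reads, 2681 on numbers 3 to 7 without the block, 1261 with node and lung as 1 group, and 1975 without nodes 3 and 5. Leaving out 1 library gave 2731 (node 5) to 5333 (HPN primary 1). With the keratinocyte covariate 3789 genes were called, of which 2577 were among the 4313, and 192 of the 4313 had the opposite sign. For lung against primaries (51) the count was 352 with DESeq2, 0 with limma voom, 138 with no filter, 12 with a filter of over 1 CPM, 89 with all 4 groups, 1 without low-quality reads, 0 on numbers 3 to 7 without the block and 0 with a random block. Leaving out 1 library gave 0 (lung 4) to 393 (lung 3). For lung against node (966) it was 2467 with DESeq2, 263 with the batch as a term, 0 without low-quality reads, 526 on numbers 3 to 7 without the block and 30 with a random block. Leaving out 1 library gave 0 (lung 4) to 2017 (node 4). The 12 genes higher at both sites became 0 as the median of 35 splits of the primaries. They also became 0 at an adjusted p under 0.01, a bound that no gene in lung reached in edgeR. DESeq2 size factors moved no count by over 1.5 times.

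With the replicate block, the fit is restricted to shared title numbers. It called 1307 genes for nodes, of which 1253 were among the 4313, 0 for lung and 0 for lung against node. On the same libraries without the block the counts were 2681, 0 and 526, so the smaller set of libraries accounts for part of the change. Of list calls, the block lost 1 of 5 and gained 7 for the genotypes, lost 2 of 22 and gained 0 for nodes, lost 5 of 15 and gained 2 for lung, and lost 4 of 18 and gained 4 for lung against node. Of named genes fitted under it, 61 of 111 for nodes, 12 of 14 for lung and 47 of 49 for lung against node lost their call, and none changed sign.

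The 24 changes of sign of named genes were in Nme1 or came without lung 4. For Nme1 in lung the log2 difference was 0.013 without low-quality reads, 0.024 without HPN primary 3, 0.012 without HPN primary 7 and 0.075 without lung 4 (lowest -0.14, without HPN primary 1). Without lung 4, which leaves 1 lung sample taken to vary like the other groups, the fitted values for lung against primary were -1.69 for Sftpa1, -6.04 for Sftpb, -4.99 for Myh6, -4.55 for Sec14l3, -5.76 for Bpifa1, -5.12 for Cxcl15, -1.76 for Mlc1, -4.20 for Lamp3, -3.75 for Cyp2a5 and -0.17 for Prx; the highest values, all without lung 3, were 11.14 for Cxcl15, 10.92 for Mlc1, 10.86 for Lamp3, 10.67 for Cyp2a5 and 3.95 for Prx. For lung against node the fitted values were -6.22 for Sftpb, -5.45 for Bpifa1, -2.10 for Sftpa1, -3.70 for Actc1, -4.64 for Cxcl15, -5.27 for Myh6, -4.59 for Sec14l3, -0.77 for Slc34a2, -3.07 for Sftpc and -0.27 for Ager (highest 6.72, without lung 3). Of these genes lung 3 had over 3 counts only of Prx, Slc34a2, Sftpc and Ager. It had 2 counts of Sftpa1 and 0 of the others, and the primaries had 2 counts of Mlc1, so apart from those 4 genes the fitted falls are set by the prior count and show no measured fall, and no fold of Mlc1 is measured in either direction. Of 60 called lists, 60 were the same with DESeq2 size factors, 60 lost their call with an estimated correlation, and fry kept 20 and lost 40. Leaving out 1 library or another ended 3 of 5 list calls for the genotypes, 6 of 22 for nodes, 13 of 15 for lung and 10 of 18 for lung against node. Of the 635 values of called lists in these fits, the median changed sign in 9, with the direction of the test in 5 of them. In the genotypes these were skeletal muscle without HPN primary 1 (median 1.05 to -0.49) and glycolysis without HPN primary 7 (0.32 to -0.090). The other 7 came without lung 4 (both lung epithelium medians stay negative, at -1.15 and -1.10, with members at 3 counts or fewer set to a floor of 3 counts), and in 2 of them the list was called the other way: endothelial genes (0.97 to -0.69) and mitosis genes (-0.31 to 0.38) in lung. Low counts limit Nme2, at 2 to 41 per primary library, and what keeps them low was not tested. With 2 lung libraries the simulation, in genes of at least 5 CPM, found 14% of those changed by log2 1 and 81% of those by log2 3.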

Other observations

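The test of single genes in this part was chosen after their values were seen, and it gives values with no p.

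Genes of mesothelium and heart muscle were also present in lung 4. Msln and Upk3b, which mark mesothelium, were at 89.8 and 62.7 CPM in lung 4 and at 0.417 and 0.642 CPM in lung 3, with at most 0.192 and 0.738 CPM in any HPN primary. Wt1, a transcription factor of mesothelium, was at 4.97 and 0.514 CPM. Tnni3 and Myh7, genes of heart muscle, were at 41.6 and 6.19 CPM in lung 4 and at 0.289 and 0 CPM in lung 3. Melanocyte genes were present in both lungs. Dct, an enzyme of melanin synthesis, was at 13040 CPM in lung 4 and 19710 CPM in lung 3 (3031 to 27820 CPM in HPN primaries), Tyr, the tyrosinase gene, at 1478 and 2217 CPM (489.8 to 2326), and Pmel at 2054 and 3643 CPM (1052 to 16350). Mlana was at 250.1 CPM in lung 4 and at 110.6 CPM in lung 3, which is below every HPN primary (167.1 to 711.6).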
